A study of Rattus norvegicus with 100 samples.

How the data were processed

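Total RNA from primary rat hepatocytes was measured on Affymetrix rat arrays of perfect-match probes, 1 array per culture, after biotin labelling of amplified RNA with a 3′ expression kit, per the labels' protocols. The cells were plated on collagen IV under a Geltrex overlay, and the RNA was extracted with a DNase step, per the labels' protocols. The deposited values are log2 intensities, 1 per probe set and array. GCRMA and Partek are named in the submitters' processing notes without version, role or order. The arrays have close but unequal distributions (array medians from 4.13 to 4.46), so they were used as deposited, without further scaling.

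The table held 31139 probe sets. Of these 19069 had exactly 1 gene symbol (61.2%), 572 had several and 11498 had none, and gene IDs of 18989 were found in the RefSeq gene table of the rat. A gene was represented by its probe set with the highest mean over the 100 arrays, which gave 13439 genes, and 8843 with a log2 value above 5 in at least 3 arrays were tested. A value of 5 was taken as the floor: where all arrays of a group lay at or under it, the fold is printed as a lower bound against the floor. Where only some did, the lower bound is the fold with values under 5 set to 5, beside the log2 change as measured. Depth in the sense of counts does not exist for arrays, and their number limits the precision.

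One linear model with 30 group means was fitted to the 100 arrays with limma 3.58.1 in R 4.3.3 (statmod 1.5.0; figures with Python 3.11.15 and matplotlib 3.10.9), with 70 residual degrees of freedom, moderated variances and Benjamini-Hochberg adjustment over all genes tested, per comparison, two-sided, at 0.05. The comparisons were 1 µM against 0 µM at each of the 5 times, each of the 5 concentrations against 0 µM averaged over the times, 10 µM against 1 µM averaged over the times, the difference between the changes at 72 and 2 h, and 72 h against 2 h at 0 µM. Counts for each time and concentration come from the same model. These choices, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise.

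Genes are named by a fixed rule. It takes for each comparison up to 15 rises and 15 falls, by size among genes past the threshold with the same sign in every rat that had both arrays (a condition dropped for the difference between 72 and 2 h), then up to 6 members per gene list and comparison by p, any list member that did not pass, and a fixed set of known PPARα targets. The text prints part of what the rule allows. In all, 23 gene lists were fixed: mitochondrial fatty acid oxidation and carnitine shuttle, peroxisomal oxidation and biogenesis, acyl-CoA thioesterases, lipid droplets and lipolysis, microsomal ω-oxidation, ketone bodies, fatty acid uptake and activation, other PPARα-responsive genes, genes typical of fat cells, cholesterol synthesis, lipogenesis, bile acids, xenobiotic metabolism, NRF2 response, ATF4 and unfolded protein response, cell cycle, acute phase, glucose and amino acid metabolism, hepatocyte identity, and markers of macrophages, stellate cells, endothelium and bile ducts. Members without a named probe set or under the filter were not analysed here, and the endothelial list, with 1 measured member, was not tested. Lists were tested with camera of limma (inter-gene correlation preset to 0.01, adjusted over the 22 lists of a comparison), and again with the correlation estimated from the residuals. Camera ranks a list against the other genes, so that its direction can differ in sign from the median of a list.

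Each rat gave cultures to many groups, so the arrays of one rat are paired by animal, per the labels. Deviations from the group means had a median correlation of 0.62 between arrays of the same rat (lowest rat 0.519) and -0.22 between arrays of different rats, and the nearest array was of the same rat for 94 of 100. The model without the rat is the primary one, and the rat as a block is an alternative. Its value is printed beside a result or in the closing section where it changes the call or moves the count of one of these comparisons by more than 1.5 times. Block values of the further counts per time and concentration are not printed. The array plate positions in the labels are spread over times, concentrations and rats. They cannot be those of a single plate, since 10 of 87 positions are given to 2 or 3 arrays (23 arrays, among them all 5 of low signal), and the labels of 5 arrays, none of low signal, end in 2. Plates, dates and batches are not named, so values within a plate could not be computed, and these arrays were left out instead.

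The alternatives were the rat as a block, the arrays of the compared times alone, one value per rat for the averages, no filter, a filter at log2 7, an intensity trend with a robust prior, quantile normalization, median centring, every probe set as its own feature (15873 past the filter), a minimum of 1.5-fold, and leaving out each rat. Of those added later, one left out the 5 arrays whose 75th percentile lay under 6.6, one the 23 arrays at repeated positions, one the 5 arrays whose label ends in 2, and one exchanged the rats of 2 arrays in the block. Other splits of the arrays were enumerated, or 100 were drawn with a fixed seed. For the averages and the difference between 72 and 2 h, further splits exchanged the compared arrays only within a rat and time.

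The procedure was tested on simulated data with 200 of 8843 genes changed between 1 µM and 0 µM at 72 h. It called 43.3% of those changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 7 calls among unchanged genes. With the rat as a block it called 43.3%, 85.1% and 98.5%, with 10 such calls. In the list test the changed list was called (adjusted p = 4.86e-40) and 0 of 20 unchanged lists. The simulated noise was independent between genes and arrays, with no effect of the rat and no arrays of low signal. These values therefore show that the procedure runs as intended and do not give its error rates on the real arrays.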

Results

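GW7647, a synthetic activator of the nuclear receptor PPARα, was added to primary rat hepatocytes at 0.001, 0.01, 0.1, 1 or 10 µM or left out (0 µM), and RNA was collected after 2, 6, 12, 24 and 72 h. PPARα controls genes of fatty acid use in the liver. The hepatocytes came from 4 rats (Rs627, Rs628, Rs631 and Rs632), and each of the 100 arrays measured one culture from one rat. The 30 groups of time and concentration held 2 to 4 arrays each. At 0 µM there were 3, 4, 3, 3 and 4 arrays at 2, 6, 12, 24 and 72 h, and at 1 µM there were 3, 4, 4, 4 and 4. The labels do not say whether the 0 µM cultures received the solvent of the agent. The values were log2 intensities, and 8843 of 13439 genes with a probe set exceeded a log2 value of 5 in at least 3 arrays and were tested. The 75th percentile of an array, taken here as its overall signal, ranged from 6.42 to 7.27. It lay under 6.6 in 5 arrays, namely Rs631 at 0.1 µM and 2 h, Rs627 at 10 µM and 6 h, Rs631 at 10 µM and 24 h, and Rs631 and Rs632 at 1 µM and 24 h. The lowest of the other 95 arrays lay close above that bound, at 6.63. The group at 0.01 µM and 72 h had a mean of 6.73. The labels give a plate position per array, and 10 of the 87 positions are given to 2 or 3 arrays. These 23 arrays at repeated positions include all 5 of low signal. The number of arrays limits the precision. Errors are standard errors of the log2 change from the fit unless given as SD, and adjusted p-values are those of limma.

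The first question was which genes responded to the agent over time, and it was read at 1 µM, the concentration with most arrays. Of the 20 measured genes of mitochondrial oxidation and the carnitine shuttle, 3 passed the test at 2 h, 14 at 6 h, 19 at 12 h and 20 at both 24 and 72 h. Of the 21 genes of peroxisomal oxidation and peroxisome assembly, 2, 12, 15, 16 and 19 passed, each of them higher at 1 µM. Over all genes, 33 differed from 0 µM at 2 h (31 higher, 2 lower), 180 at 6 h (153 and 27), 478 at 12 h (350 and 128), 2619 at 24 h (624 and 1995) and 2373 at 72 h (998 and 1375). With the rat as a block in the model the counts were 74, 416, 998, 4405 and 3564, of which 8, 155, 377, 3396 and 2123 fell, so that the falls grew by a larger factor than the rises at every time. At 24 h the median change of all genes at 1 µM was -0.23, and the group held 2 of the 5 arrays of low signal (mean 75th percentile 6.69 ± 0.26 SD, n = 4, against 6.99 ± 0.11, n = 3, at 0 µM).

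**Figure D1:**
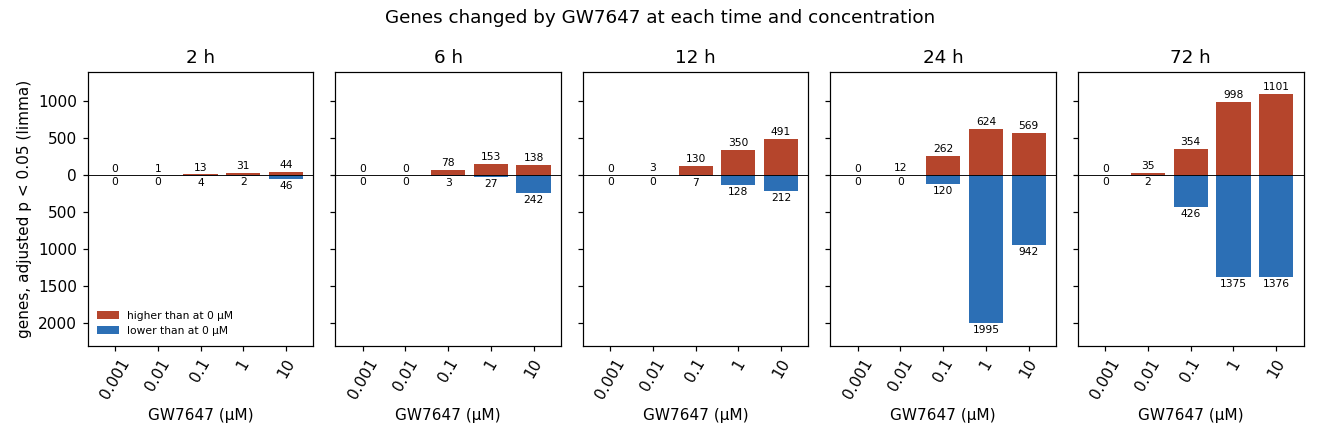
Number of genes (vertical axis) higher (upward bars) or lower (downward bars) than at 0 µM at each GW7647 concentration in µM (horizontal axis) and time (panels), at an adjusted p under 0.05 in limma. No gene passed at 0.001 µM at any time, and 998 rose and 1375 fell at 1 µM at 72 h; the 1995 falls at 1 µM and 24 h were 699 after median centring.

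At 2 h, the shortest exposure, Pdk4, whose product restrains pyruvate dehydrogenase, rose 14.7-fold (log2 change 3.88 ± 0.49, adjusted p = 7.87e-08, n = 3 and 3). Its log2 value was 12.23 ± 0.07 (SD) at 1 µM and 8.35 ± 1.26 at 0 µM, and without Rs627 its log2 change was 4.60. Txnip, a thioredoxin-binding protein, rose 4.01-fold (2.00 ± 0.31, adjusted p = 1.75e-05). Ehhadh, the bifunctional enzyme of peroxisomal β-oxidation, rose 3.40-fold (1.76 ± 0.28, adjusted p = 4.58e-05), and Angptl4, a secreted inhibitor of lipoprotein lipase, rose 3.26-fold (1.71 ± 0.17, adjusted p = 4.40e-11). These changes had the same sign in both rats with an array in each group. Acot1, an acyl-CoA thioesterase, rose at least 7.11-fold with values under 5 set to 5 (log2 change as measured 3.63 ± 0.75, adjusted p = 0.00365) and was above 5 in 3 of 3 treated arrays and 1 of 3 at 0 µM. Cyp4a1, a fatty acid ω-hydroxylase, rose 2.91-fold (1.54 ± 0.31, adjusted p = 0.00246). The 2 genes that fell were Kcnk5, a potassium channel (2.05-fold, -1.03 ± 0.23, adjusted p = 0.0114), and Znf750, a zinc-finger factor (2.12-fold, -1.08 ± 0.25, adjusted p = 0.0174). Cpt1a, which loads long-chain fatty acids onto carnitine, missed the threshold (1.83-fold, 0.87 ± 0.28, adjusted p = 0.379) and passed it with the rat as a block (adjusted p = 0.00163). Fgf21, a liver hormone of fasting, was 2.30-fold higher without passing (adjusted p = 0.578), and Ppara itself was at or under a log2 value of 5 in all 6 arrays.

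The number of genes at 2 h was lower whichever rat was left out, which also leaves fewer arrays. It was 10 without Rs632, 17 without Rs628, 21 without Rs627 and 22 without Rs631, and 9 with the arrays of 2 h alone. Acot1 lost its call without Rs628 (log2 change 2.96), Rs631 or Rs632 (adjusted p = 0.126, 0.101 and 0.105) and Cyp4a1 without the same rats (0.0713, 0.0513 and 0.341). Kcnk5 lost its call without Rs627, Rs628 or Rs631 (0.386, 0.438 and 0.198) and Znf750 without Rs627, Rs628 or Rs632 (0.204, 0.126 and 0.558). All of these were also lost with the arrays of 2 h alone (0.254, 0.0980, 0.458 and 0.945 for Acot1, Cyp4a1, Kcnk5 and Znf750). The log2 changes behind the calls lost without a rat kept their sign. They were 2.96 to 3.87 for Acot1, 1.39 to 1.54 for Cyp4a1, -1.20 to -0.81 for Kcnk5 and -1.14 to -0.95 for Znf750.

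Among the gene lists at 2 h, few single members passed but several lists were shifted upward against the other genes. Mitochondrial oxidation had 3 members up and 17 not passing (5 up when adjusted over the list alone) with a median change of 0.23 (camera adjusted p = 4.01e-20). Peroxisomal oxidation had 2 of 21 up (4 over the list alone, 1.14e-15), acyl-CoA thioesterases 2 of 6 (3 over the list alone, 1.04e-08), lipid droplet proteins and lipolysis 2 of 11 (2 over the list alone, 1.24e-10), microsomal ω-oxidation 1 of 6 (2 over the list alone, 5.86e-04) and other PPARα-responsive genes 3 of 21 (5 over the list alone, 5.98e-16). The list of hepatocyte identity shifted downward with none of its 18 members passing (median -0.07, adjusted p = 5.86e-04). At 2 h the 0 µM arrays were of Rs627, Rs631 and Rs632 and the 1 µM arrays of Rs628, Rs631 and Rs632. Without the rat in the model, a difference between Rs627 and Rs628 can therefore enter shifts as small as this. The NRF2 list (downward, 0.00414) and the ATF4 list (upward, 0.00414) had no member passing. Their adjusted p = 0.0869 and 0.125 with an estimated correlation, and 0.0627 and 0.0515 with the rat as a block. With the block, 5 lists that were not called otherwise passed: ketone body metabolism (0.0425), fatty acid uptake (0.00757), genes typical of fat cells (0.00792) and xenobiotic metabolism (0.00694) upward, and acute phase genes (0.00757) downward. The NRF2 shift was also lost without Rs627 (0.210) and the ATF4 shift without Rs627 (0.137) or Rs628 (0.161).

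At 6 h the enzymes that carry fatty acids into mitochondria had risen. Cpt1a was 3.34-fold higher (1.74 ± 0.24, adjusted p = 1.24e-07, n = 4 and 4), Cpt2, the inner-membrane acyltransferase, 2.23-fold (1.16 ± 0.15, adjusted p = 9.51e-09) and Slc25a20, the carnitine-acylcarnitine carrier, 2.02-fold (1.01 ± 0.12, adjusted p = 1.41e-09). Ehhadh reached 11-fold (3.46 ± 0.24, adjusted p = 1.44e-18), Pdk4 7.23-fold (2.85 ± 0.42) and Fabp1, the liver fatty acid binding protein, 5.11-fold (2.35 ± 0.39). Gk, which makes glycerol 3-phosphate, rose 3.94-fold (1.98 ± 0.25), Elovl6, a fatty acid elongase, 3.74-fold (1.90 ± 0.27), Pex11a, a factor of peroxisome division, 3.26-fold (1.70 ± 0.31), Acot12 2.61-fold (1.38 ± 0.22) and Pnpla2, the triglyceride lipase of lipid droplets, 2.35-fold (1.23 ± 0.15). Acat1, an enzyme of ketone body and isoleucine metabolism, rose 2.07-fold (1.05 ± 0.11) and Creb3l3, a liver transcription factor of lipid metabolism, 2.03-fold (1.02 ± 0.15). Kcnk5 fell 2.09-fold (-1.06 ± 0.20, adjusted p = 1.71e-04). Each of these had the same sign in all 4 rats, and their adjusted p-values ran from 1.44e-18 to 1.71e-04. The count of 180 genes was 104 without Rs632 and 109 without Rs627.

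At 6 h, 14 of 20 genes of mitochondrial oxidation (18 adjusted over the list alone, camera adjusted p = 8.79e-68), 12 of 21 of peroxisomal oxidation (12 over the list alone, 8.94e-38), 4 of 6 thioesterases (4, 7.19e-21), 6 of 11 lipid droplet genes (7, 4.00e-25) and 9 of 21 other PPARα-responsive genes (12, 4.34e-21) were up, with none down. Smaller numbers were up in ω-oxidation (3 of 6, 2.24e-06), ketone body metabolism (2 of 5, 1.03e-04), fatty acid uptake, binding and activation (3 of 15, 3.99e-10) and lipogenesis (3 of 16, 7.26e-07). These 9 lists were also called with an estimated correlation. Upward calls of genes typical of fat cells (0.0290), cholesterol synthesis (0.00539), xenobiotic metabolism (0.0176) and glucose and amino acid metabolism (0.0369) were lost with it, at adjusted p = 0.0722, 0.302, 0.120 and 0.241 with an estimated correlation. The glucose list was also lost without Rs627 (0.0837), Rs632 (0.107) or the arrays at repeated positions (0.0699), the fat cell list without the latter (0.185), and the xenobiotic list without Rs628 (0.0719).

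At 12 h Ehhadh was 19-fold higher (4.25 ± 0.26, adjusted p = 1.10e-21, n = 4 and 3). Cpt1b, the carnitine palmitoyltransferase typical of muscle, was 8.28-fold higher (3.05 ± 0.38, adjusted p = 1.65e-09) and Hacl1, of peroxisomal α-oxidation, 7.38-fold (2.88 ± 0.26, adjusted p = 1.31e-14). Fabp3, the heart fatty acid binding protein, was at or under a log2 value of 5 at 0 µM and at least 10.6-fold higher at 1 µM (adjusted p = 3.52e-10). Aqp3, a water and glycerol channel, was above 5 in 3 of 4 treated arrays and in none at 0 µM (at least 6.04-fold, adjusted p = 0.00184), a call lost without Rs627 (adjusted p = 0.0957). Its log2 change of 4.45 was 5.44 without Rs631 and 5.45 without the arrays whose label ends in 2. Fads2, a fatty acid desaturase, rose 3.26-fold (1.71 ± 0.32, adjusted p = 8.11e-05) and Vnn1, a pantetheinase, 1.77-fold (0.83 ± 0.20, adjusted p = 0.00369, lost without the arrays at repeated positions at 0.0602). Arrdc4, an arrestin-like protein, fell 2.62-fold (-1.39 ± 0.23, adjusted p = 3.90e-06) and Pkdcc, a secreted kinase, 3.54-fold (-1.82 ± 0.36, adjusted p = 1.43e-04), the latter lost without Rs631 (adjusted p = 0.0625). Each of these had the same sign in all 3 rats with both arrays. The count of 478 genes was 259 with the arrays of 12 h alone, 284 without Rs627 and 729 without Rs628. Without Rs628 371 rose and 358 fell, so that the excess of rises was nearly gone, and after quantile normalization 379 rose and 258 fell. The 0 µM arrays labelled Rs627 and Rs628 at this time resembled the other rat of the pair, as set out in the closing section, so that the signs by rat and the values without Rs627 or Rs628 rest on the labels as given.

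At 12 h, 19 of 20 genes of mitochondrial oxidation, 15 of 21 of peroxisomal oxidation, 4 of 6 thioesterases, 7 of 11 lipid droplet genes, 7 of 15 uptake genes and 11 of 21 other PPARα-responsive genes were up and none down (20, 17, 5, 7, 8 and 13 up when adjusted over each list alone, with 1 of the last list down). Their camera adjusted p-values ran from 1.08e-63 to 2.49e-10. Lipogenesis had 7 of 16 up (4.50e-09), ω-oxidation 3 of 6 (1.71e-04) and ketone body metabolism 2 of 5 (1.21e-04). Upward calls of cholesterol synthesis (0.0372) and glucose metabolism (0.00494) were lost at adjusted p = 0.499 and 0.101 with an estimated correlation, and the former also without Rs627 (0.0879) or Rs628 (0.152) and the latter without the arrays at repeated positions (0.202). The acute phase list had no member passing (adjusted p = 0.160) and was called downward with the rat as a block (0.0479) and without the arrays at repeated positions (3.42e-04).

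At 24 h Acot1 was at or under a log2 value of 5 in all 0 µM arrays and at least 125-fold higher at 1 µM (11.97 ± 0.19 SD, n = 4, adjusted p = 1.83e-14). Fabp3 was at least 22.5-fold higher, Aqp3 at least 10.9-fold (above 5 in 3 of 4 treated arrays), Cxcl12, a chemokine, at least 7.86-fold and Cacna2d3, a calcium channel subunit, at least 4.80-fold. Ehhadh rose 20.1-fold (4.33 ± 0.26), Cpt1b 11-fold (3.46 ± 0.38), Acadm, the medium-chain acyl-CoA dehydrogenase, 3.76-fold (1.91 ± 0.17) and Hadha, of the mitochondrial trifunctional protein, 2.83-fold (1.5 ± 0.09). Fads2 rose 5.05-fold (2.34 ± 0.32) and Pc, pyruvate carboxylase, 4.44-fold (2.15 ± 0.40). The log2 change of Fabp3 was 5.58 and 6.39 without Rs631, and that of Aqp3 4.98, 4.37 without Rs627 and 6.43 without Rs631. Among the falls were Abcc2, the canalicular exporter of conjugates (5.32-fold, -2.41 ± 0.40), Pklr, liver pyruvate kinase (at least 5.12-fold, -2.40 ± 0.47 as measured, above 5 in 3 of 4 treated arrays), Klkb1, plasma prekallikrein (at least 4.54-fold, above 5 in 2 of 4), and Cebpd, a transcription factor of the acute phase (at least 4.16-fold, above 5 in 2 of 4). Kmo, of tryptophan breakdown, was under 5 in all treated arrays and at least 3.43-fold lower. Ass1, of the urea cycle, fell 2.58-fold (-1.37 ± 0.22) and Srxn1, which repairs oxidised peroxiredoxins, 2.48-fold (-1.31 ± 0.23). The adjusted p-values of these genes lay between 1.32e-22 and 4.62e-04, and each had the same sign in all 3 rats with both arrays.

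The balance of rises and falls at 24 h moved with the scaling and with the arrays of low signal. Without the 5 arrays of low signal, and also without the arrays at repeated positions, the log2 changes of Fabp3 and Aqp3 were 6.74 and 6.55. After centring each array on its median, which itself fixes the balance, 1384 genes rose and 699 fell, after quantile normalization 907 rose and 1391 fell, and without the 5 arrays of low signal 585 rose and 707 fell. Without the arrays at repeated positions 622 rose and 791 fell. The count of 2619 was 867 without Rs632 and 1484 without Rs631.

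At 24 h all 20 genes of mitochondrial oxidation rose (median change 1.31, camera adjusted p = 1.19e-54), with 16 of 21 of peroxisomal oxidation, 4 of 6 thioesterases, 7 of 11 lipid droplet genes and 7 of 16 of lipogenesis (1 down). Other PPARα-responsive genes had 13 up and 2 down of 21, fatty acid uptake 8 up and 2 down of 15, glucose and amino acid metabolism 5 up and 2 down of 14, ω-oxidation 3 up and 1 down of 6 and ketone body metabolism 2 up and 1 down of 5. These 10 lists were called upward with either correlation (preset adjusted p at most 0.00108). Of the NRF2 oxidative stress list, 6 of 11 members fell and none rose (7 fell when adjusted over the list alone, camera adjusted p = 0.0331, adjusted p = 0.189 with an estimated correlation). That call was lost without Rs627 (0.0967) or Rs628 (0.117). Genes typical of fat cells had 1 of 4 up (0.0307, adjusted p = 0.0641 with an estimated correlation), lost without Rs631 (0.0964) or the arrays at repeated positions (0.257). The acute phase list had 6 of 17 down and none up without a shift against other genes (0.556), which passed with the rat as a block (0.0272).

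**Figure D2:**
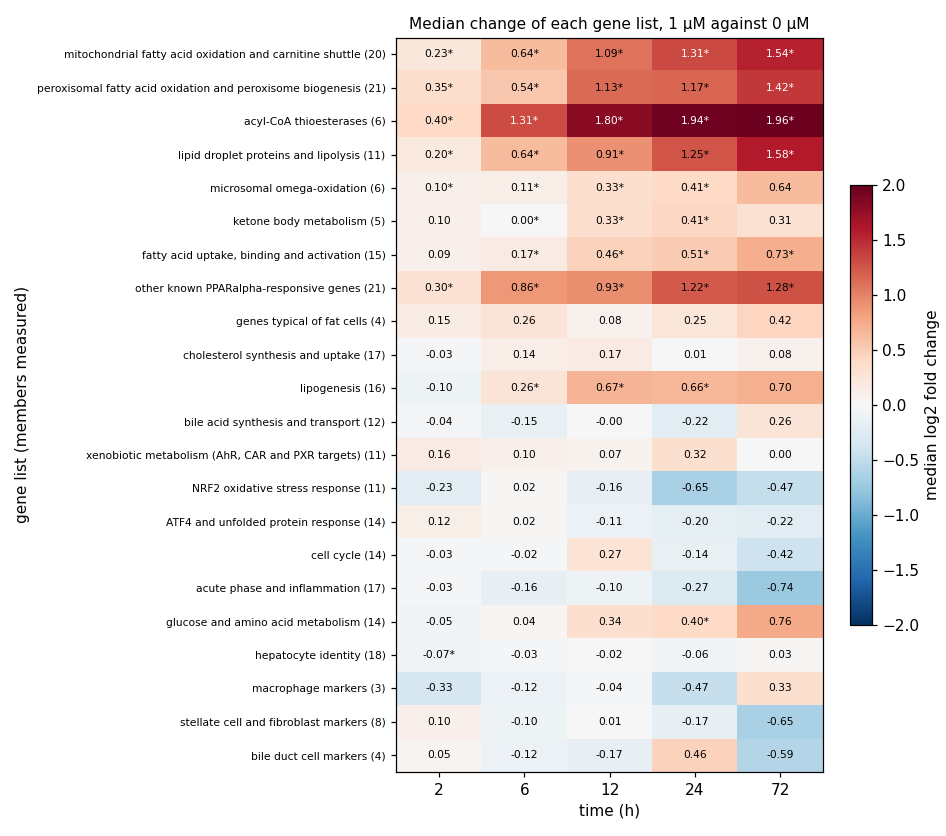
Median log2 change of the members of each gene list (vertical axis, number of measured members in brackets) at 1 µM against 0 µM over time in h (horizontal axis), coloured by size and starred where camera with an estimated correlation gave an adjusted p under 0.05. The median of mitochondrial oxidation went from 0.23 at 2 h to 1.54 at 72 h.

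Many genes of fatty acid use rose several-fold at 72 h. A sign of RNA quality also differed between the groups at this time: the 3′ minus 5′ log2 value of β-actin was 1.97 at 1 µM and 1.66 at 0 µM, higher at 1 µM by 0.14 to 0.58 in 4 of 4 rats, and 1.90 to 1.95 at 0.01, 0.1 and 10 µM. That of GAPDH was 0.337 and 0.348. From 0.01 to 10 µM the β-actin value did not follow the number of changed genes. It was 1.94 at 0.01 µM, where 37 genes passed at 72 h, and 1.97 at 1 µM, where 2373 did. At 0.001 µM, where no gene passed, it was 1.70, near that at 0 µM. A part of RNA quality in the calls at 72 h is therefore not excluded. Acot1 was at least 133-fold higher (12.05 ± 0.14 SD at 1 µM, n = 4, at or under 5 at 0 µM, n = 4, adjusted p = 3.63e-17). Fabp3 was at least 29.6-fold higher (log2 change 6.15, 6.75 without Rs631). Ehhadh rose 28.2-fold (4.82 ± 0.24, adjusted p = 2.34e-27), Cpt1b 19.6-fold (4.29 ± 0.35), Fabp1 17.6-fold (4.14 ± 0.39), Pdk4 17.6-fold (4.13 ± 0.42) and Cyp4a1 7.92-fold (2.98 ± 0.27). Genes outside fatty acid use rose as well. Aqp3 was at least 24.8-fold higher (log2 change 6.4, 7.12 without Rs631). Serpine2, a protease inhibitor, was at least 19.1-fold higher, Adig, known from fat cells, at least 13.1-fold, Cxcl12 at least 10.1-fold and Cacna2d3 at least 9.57-fold, each from values at or under 5 at 0 µM. The genes of this paragraph and the next had adjusted p-values from 6.60e-31 to 6.16e-07 and the same sign in all 4 rats.

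By list, all 20 genes of mitochondrial oxidation rose at 72 h (camera adjusted p = 6.45e-46), among them Hadha (3.26-fold, 1.70 ± 0.09) and Slc25a20 (3.58-fold, 1.84 ± 0.12). Cpt1a, on the same list, rose 3.36-fold (1.75 ± 0.24). Of the peroxisomal list 19 of 21 rose (9.08e-32), among them Pex19, an import factor of peroxisomal membrane proteins (5.07-fold), and the peroxisomal thioesterase Acot8 (5.45-fold). Thioesterases had 5 of 6 up (4.27e-10). Of the lipid droplet list 7 of 11 rose (2.59e-11), among them Mgll, monoglyceride lipase (3.84-fold), Pnpla2 (3.57-fold), Cidea, a droplet protein typical of brown fat (3.48-fold), and Plin2, a droplet coat protein (1.61-fold). Fatty acid uptake and activation had 8 up and 2 down of 15 (2.87e-06), with Acsl1, an acyl-CoA synthetase, up 4.62-fold. Other PPARα-responsive genes had 15 up and 2 down of 21 (1.98e-11, 17 up over the list alone), among them Gk (6.81-fold), Vnn1 (2.42-fold), Creb3l3 (2.21-fold) and Angptl4 (1.92-fold). Acat1 rose 5.50-fold.

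Further lists at 72 h were called upward with the preset correlation only. Lipogenesis had 8 of 16 up and none down (11 up over the list alone, 1.64e-06, adjusted p = 0.0615 with an estimated correlation), among them Fads2 (6.00-fold, 2.59 ± 0.30, adjusted p = 6.80e-11) and Dgat1, which completes triglyceride synthesis (2.78-fold, 1.47 ± 0.15, adjusted p = 3.11e-13). Glucose and amino acid metabolism had 6 up and 2 down of 14 (0.00169, adjusted p = 0.0670 with an estimated correlation), with Pc up 4.49-fold (2.17 ± 0.37, adjusted p = 2.22e-06). Microsomal ω-oxidation had 4 up and 1 down of 6 (0.00169, adjusted p = 0.0527 with an estimated correlation). Ketone body metabolism had 3 up and 1 down of 5 (0.0109, adjusted p = 0.0699 with an estimated correlation, 0.0565 with the rat as a block). Genes typical of fat cells had 1 of 4 up (0.0322, adjusted p = 0.0756 with an estimated correlation), lost without Rs628 (0.0692) or Rs631 (0.0613). Fgf21 rose 2.20-fold (1.14 ± 0.36, adjusted p = 0.0112, lost without Rs627 at 0.0727). Ppara was above 5 in 3 of 4 treated arrays and in none at 0 µM (at least 1.14-fold, adjusted p = 0.0127), lost without Rs627 (0.106) or Rs628 (0.168).

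Part of the acute phase and oxidative stress genes fell at 72 h. Of the acute phase and inflammation list 9 of 17 fell and none rose (9 over the list alone, median change -0.74, camera adjusted p = 0.00138, adjusted p = 0.311 with an estimated correlation). Among them were Icam1, an adhesion receptor (2.86-fold, -1.52 ± 0.28, adjusted p = 1.01e-05), and Stat3, which carries interleukin signals (1.52-fold, -0.60 ± 0.13, adjusted p = 2.53e-04). Of the NRF2 list 5 of 11 fell and none rose (0.0173, adjusted p = 0.136 with an estimated correlation), among them Srxn1 (2.29-fold, -1.20 ± 0.21, adjusted p = 4.25e-06).

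Genes of several other kinds fell strongly at 72 h. Cyp2c11, a cytochrome P450 typical of the male rat liver, fell at least 19.8-fold with values under 5 set to 5 (-4.82 ± 0.87 as measured, adjusted p = 8.82e-06, above 5 in 2 of 4 treated arrays), Cav1, the coat protein of caveolae, at least 11.8-fold (-4.62 ± 0.85, adjusted p = 1.16e-05, above 5 in 1 of 4) and S100a6, a calcium-binding protein, at least 19.4-fold (-4.35 ± 0.51, adjusted p = 1.07e-10, above 5 in 3 of 4). Gna14, a G protein subunit, was at least 8.51-fold lower and Pla2r1, a phospholipase receptor, at least 7.81-fold, both at or under 5 in all 4 treated arrays. Ccn2, a secreted matrix-associated protein, fell 12.5-fold (-3.64 ± 0.57, adjusted p = 4.31e-07) and Gpnmb, a transmembrane glycoprotein, 8.87-fold (-3.15 ± 0.46, adjusted p = 8.42e-08). Abcc2 fell 5.33-fold (-2.42 ± 0.37, adjusted p = 2.48e-07). Without the arrays at repeated positions the log2 changes of Cav1, S100a6 and Ccn2 were -5.44, -4.93 and -4.33. The β-actin values given above differed between the same groups. At 0.01 µM, where the β-actin value was also high, Ccn2 was 11.77 to 12.70. This was lower than at 0 µM in each of the 4 rats, but above every value at 1 µM. Its values were 12.27 to 12.84 at 0 µM and 7.53 to 10.92 at 1 µM.

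Markers of hepatocyte identity went both ways at 72 h, with 5 of 18 up, 6 down and 7 not passing (camera adjusted p = 0.512). Serpina1, the main plasma antitrypsin, fell 1.84-fold (-0.88 ± 0.12), Ahsg, a plasma glycoprotein, 2.83-fold (-1.50 ± 0.17) and Ass1 3.16-fold (-1.66 ± 0.20), while Cyp2e1, an ethanol-oxidising P450, was at least 4.57-fold higher. Their adjusted p-values lay between 9.97e-11 and 3.91e-08. Of the 8 measured stellate cell and fibroblast markers 4 fell and none rose (0.192), among them the filament protein Vim (3.28-fold, -1.71 ± 0.46, adjusted p = 0.00280, lost without Rs632 at 0.0602) and Acta2, smooth muscle actin (1.47-fold, -0.55 ± 0.15, adjusted p = 0.00248). Of 3 macrophage markers Lyz2, lysozyme, fell 4.36-fold (-2.13 ± 0.32, adjusted p = 1.14e-07), Cd14 rose 1.78-fold (0.83 ± 0.26, adjusted p = 0.0103, lost without Rs627 at 0.0821 or Rs632 at 0.0779) and Cd68 did not pass (0.33 ± 0.67, adjusted p = 0.779). None of 4 bile duct markers passed, among them Spp1 (0.38 ± 0.28, adjusted p = 0.345), and the 1 measured endothelial marker, Eng, was under 5 in all 8 arrays. The count of 2373 genes was 1520 without Rs627, and after median centring 1291 rose and 1158 fell.

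**Figure D3:**
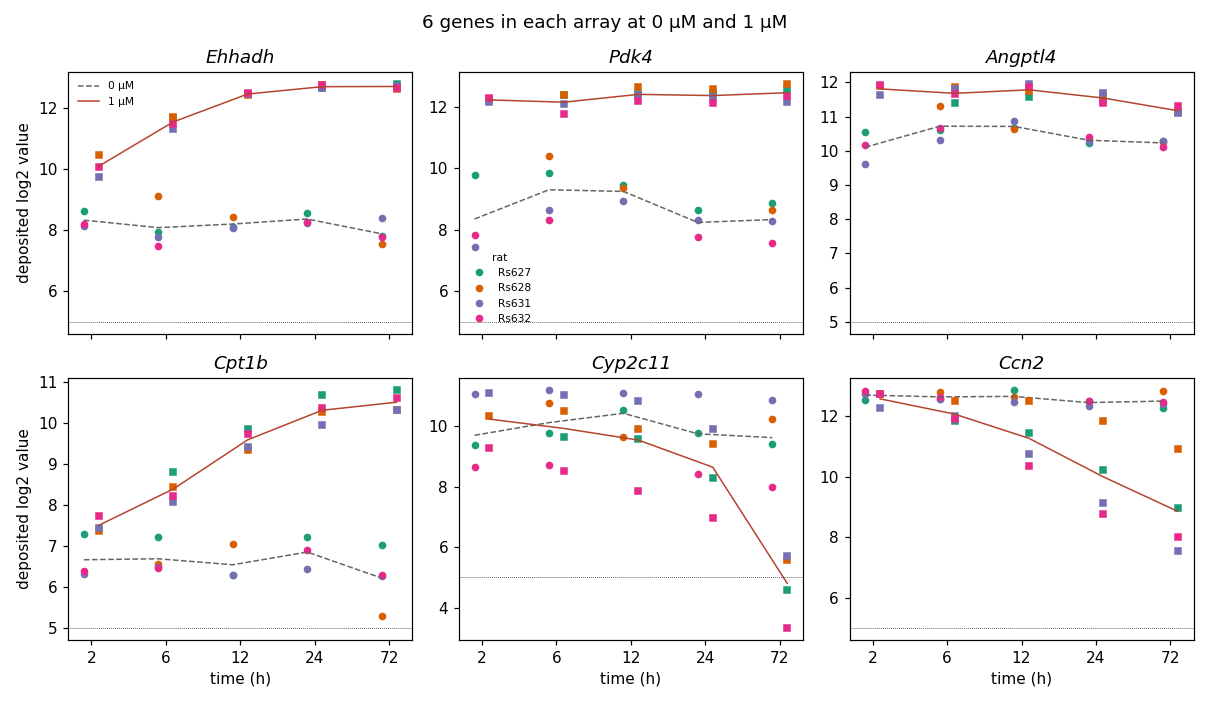
Deposited log2 value (vertical axis) of 6 genes in each array at 0 µM (circles, dashed mean) and 1 µM (squares, solid mean) over time in h (horizontal axis, not to scale), coloured by rat; the dotted line marks a log2 value of 5. At 72 h the Cpt1b mean was 10.51 at 1 µM and 6.22 at 0 µM, and that of Ccn2 was 8.85 and 12.50.

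Whether the change at 1 µM differed between the first and the last time was tested as a difference of differences. The change was larger at 72 h for Cpt1b (by 3.45 ± 0.53, adjusted p = 1.49e-06), Fabp1 (3.27 ± 0.60, adjusted p = 5.62e-05) and Ehhadh (3.05 ± 0.37, adjusted p = 4.81e-09), 3 genes of fatty acid use. Pdk4 differed by 0.25 ± 0.65 and did not pass (adjusted p = 0.884). Angptl4 went the other way, its rise at 72 h being smaller by 0.76 (-0.76 ± 0.23, adjusted p = 0.0222), a call lost after median centring (0.126) and without Rs628 (0.0946), Rs631 (0.128) or Rs632 (0.167). The difference was negative for S100a6 (-4.37 ± 0.78, adjusted p = 3.58e-05, -4.96 without the arrays at repeated positions) and Cyp2c11 (-5.36 ± 1.33, adjusted p = 0.00425, lost without Rs627 at 0.0963), which fell at 72 h. Altogether 766 genes differed (389 upward and 377 downward), 1584 with the rat as a block (685 and 899). It was 1235 without the arrays at repeated positions (542 and 693). The count was 303 without Rs627 and 305 without Rs632, and 462 went upward and 300 downward after median centring.

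By list, 19 of 20 genes of mitochondrial oxidation (camera adjusted p = 3.17e-41), 14 of 21 of peroxisomal oxidation (2.11e-27), 4 of 6 thioesterases (1.46e-07), 4 of 11 lipid droplet genes (4.12e-07) and 6 of 15 uptake genes (3.51e-06) had a larger change at 72 h and none a smaller one, with either correlation. Upward calls of other PPARα-responsive genes (5.70e-05), lipogenesis (2.92e-07), glucose metabolism (8.42e-04), ketone body metabolism (0.00763) and ω-oxidation (0.0258) were lost at adjusted p = 0.0590, 0.0516, 0.0590, 0.0590 and 0.149 with an estimated correlation. The last was also lost with the rat as a block (0.0541) and without Rs631 (0.0686). Acute phase genes shifted downward (0.00450, adjusted p = 0.393 with an estimated correlation), with 2 of 17 members passing. Genes typical of fat cells passed only with the rat as a block (0.0819 without it, 0.0233 with it).

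The second question was how the response depended on the concentration, read as the change averaged over the 5 times (15 to 19 arrays per concentration against 17 at 0 µM). At 0.001 µM no gene passed in limma (20 of 8843 at an unadjusted p under 0.05, 78 with the rat as a block). Both numbers are fewer than the 1 in 20 expected by chance, so this test was conservative and does not exclude small changes. With one value per rat none passed either, but 1996 of 8843 genes had an unadjusted p under 0.05 in limma, more than the 1 in 20 expected by chance, so small changes at this concentration are not excluded. The value of Rs628 rests on its 72 h arrays alone. Ehhadh (0.04 ± 0.12), Pdk4 (-0.16 ± 0.21) and Cyp4a1 (-0.07 ± 0.13) did not pass (adjusted p = 1.00 each). Their mean same-rat differences ran from 0.20 to 0.45 for Ehhadh and from 0.03 to 0.26 for Cyp4a1, above 0 in 4 of 4 rats, and from -0.20 to 0.13 for Pdk4. By time, the difference was above 0 in 7 of 7 pairs of arrays at 24 and 72 h for Ehhadh (0.34 to 0.86) and Cyp4a1 (0.03 to 0.45) and in 4 of 7 for Pdk4. Signs were mixed at 2 and 6 h, except that Pdk4 was below 0 in every pair at 2 h (-0.25 to -0.22). At 0.01 µM Ehhadh was 2.66-fold higher (1.41 ± 0.12, adjusted p = 5.00e-14), Pdk4 2.43-fold (1.28 ± 0.21, adjusted p = 2.84e-05), Cyp4a1 2.23-fold (1.15 ± 0.13), Fabp1 2.21-fold (1.14 ± 0.20), Crat, carnitine acetyltransferase, 1.63-fold (0.70 ± 0.10) and Acsl1 1.57-fold (0.65 ± 0.08). At 0.1 µM Ehhadh stood at 9.65-fold (3.27 ± 0.12), Pdk4 at 8-fold (3.0 ± 0.22), Cyp4a1 at 4.47-fold (2.16 ± 0.14) and Cpt1b at 4.23-fold (2.08 ± 0.18). At 1 µM the same 4 genes were 13.2-fold (3.72 ± 0.12), 12.4-fold (3.63 ± 0.20), 5.12-fold (2.36 ± 0.13) and 6.36-fold (2.67 ± 0.17) higher. At 10 µM they were 13.8-fold (3.78 ± 0.12), 12.9-fold (3.69 ± 0.21), 4.97-fold (2.31 ± 0.13) and 6.37-fold (2.67 ± 0.17) higher. The changes of these genes from 0.01 µM up had the same sign in all 4 rats and adjusted p-values of at most 6.43e-05.

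Averaged over the times, Fabp1 rose 5.85-fold at 0.1 µM, 7.13-fold at 1 µM and 7.27-fold at 10 µM, and Crat 3.66-, 5.45- and 5.78-fold. Cpt1a (3.07-fold, 1.62 ± 0.11) and Fgf21 (1.86-fold, 0.89 ± 0.17) rose at 1 µM. Ccn2 fell 3.11-fold at 1 µM (-1.64 ± 0.27) and 4.73-fold at 10 µM (-2.24 ± 0.28, -2.92 without Rs628), and Cebpd at least 2.71-fold at 1 µM (-1.58 ± 0.22 as measured, above 5 in 15 of 19 treated arrays). The numbers of genes were 61 at 0.01 µM (58 higher, 3 lower), 1263 at 0.1 µM (561 and 702), 3128 at 1 µM (1037 and 2091) and 3488 at 10 µM (1036 and 2452). With the rat as a block, 166 (133 and 33) and 2509 genes (881 and 1628) passed at 0.01 and 0.1 µM.

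These averages rest on 4 rats. With one value per rat, 1 gene passed at 0.01 µM, 604 at 0.1 µM, 2701 at 1 µM and 909 at 10 µM. Each value averages the times at which a rat had both arrays, and these times differ between rats. At 10 µM that of Rs627 rests on 2 and 6 h alone. That of Rs628 rests on 72 h alone at 0.001 and 0.1 µM. The spread between rats thus also holds differences between times. At 0.01 µM one value per rat ended the calls of Ehhadh (adjusted p = 0.0993), Pdk4 (0.141), Cyp4a1 (0.144), Crat (0.104) and Acsl1 (0.0993), although their changes stayed alike (1.42, 1.24, 1.13, 0.69 and 0.65). The calls of Pdk4 (0.313) and Fabp1 (0.262) were lost without Rs631. The count at 0.01 µM was 24 without Rs631 and 108 without Rs628. At 0.1 µM it was 605, 607 and 804 without Rs627, Rs632 and Rs631, at 1 µM 1872 without Rs632 and at 10 µM 2159 without Rs632. After median centring the rises and falls were 747 and 500 at 0.1 µM, 1569 and 1370 at 1 µM and 1822 and 1514 at 10 µM. Without the 5 arrays of low signal they were 1430 and 1789 at 10 µM. Without the arrays at repeated positions they were 679 and 564 at 0.1 µM, 1270 and 1583 at 1 µM and 1588 and 1513 at 10 µM.

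**Figure D4:**
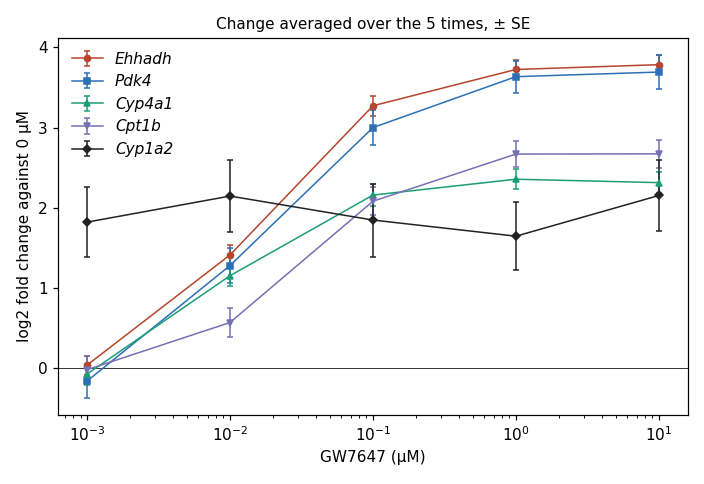
Log2 change against 0 µM averaged over the 5 times (vertical axis, points with bars of 1 SE from the fit) for 5 genes at each GW7647 concentration in µM (horizontal log axis). Ehhadh went from 0.04 at 0.001 µM to 3.78 at 10 µM, while Cyp1a2 was between 1.65 and 2.15 at every concentration.

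By list, mitochondrial oxidation had no member passing at 0.001 µM (median change -0.01), 13 of 20 up at 0.01 µM (19 adjusted over the list alone) and 20 up at 0.1, 1 and 10 µM (camera adjusted p = 7.56e-80, 7.17e-72, 2.27e-53 and 6.03e-50). Peroxisomal oxidation had 8, 17, 19 and 19 of 21 up from 0.01 to 10 µM, thioesterases 4, 4, 5 and 4 of 6, and lipid droplet genes 1, 8, 8 and 8 of 11 (7 at 0.01 µM over the list alone). Other PPARα-responsive genes had 4, 13, 16 and 16 of 21 up and 0, 2, 2 and 2 down, fatty acid uptake 2, 8, 8 and 8 of 15 up and 0, 0, 2 and 1 down, ω-oxidation 2, 3, 3 and 3 of 6 up and 0, 1, 1 and 1 down, and ketone body metabolism 1, 2, 2 and 2 of 5 up and 0, 0, 1 and 1 down. All 8 lists were called upward at these 4 concentrations with either correlation, except ketone bodies at 10 µM (0.00886, adjusted p = 0.0580 with an estimated correlation). Lipogenesis had 1, 7, 10 and 9 of 16 up and 0, 0, 2 and 2 down (0.00210, 3.05e-06, 6.93e-08 and 1.02e-07, adjusted p = 0.240, 0.0538, 0.0287 and 0.0337 with an estimated correlation), and its call at 0.01 µM was lost without Rs627 (0.0601). Acute phase genes had 0, 4, 6 and 6 of 17 down and none up. Their shift was called at 1 µM (0.0423, adjusted p = 0.616 with an estimated correlation, 0.233 without Rs627, 0.181 without the arrays whose label ends in 2) and 10 µM (0.0166, adjusted p = 0.510 with an estimated correlation). At 0.1 µM it passed only with the rat as a block (0.0503 without it, 0.00867 with it).

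Smaller upward shifts were called in other lists averaged over the times. Glucose and amino acid metabolism had 1, 5, 6 and 5 of 14 members up and 0, 1, 2 and 2 down from 0.01 to 10 µM (0.00560, 0.00226, 0.00228 and 0.00284, adjusted p = 0.112, 0.0618, 0.0627 and 0.0683 with an estimated correlation), and the first was lost without Rs627 (0.0990) or Rs631 (0.179). Genes typical of fat cells had 2 of 4 up at 0.1, 1 and 10 µM (0.00788, 0.0213 and 0.0161, adjusted p = 0.0295, 0.0568 and 0.0475 with an estimated correlation), the last lost without Rs627 (0.0592) and the last pair without the arrays at repeated positions (0.0805 and 0.121). Cholesterol synthesis was called at 0.001, 0.01 and 10 µM (0.0291, 0.0186 and 0.0466) with 0, 0 and 5 of 17 up and 1 down at 10 µM. It was lost at adjusted p = 0.556, 0.428 and 0.510 with an estimated correlation, without Rs627 at all 3 concentrations (0.504, 0.0990 and 0.108), without Rs631 at 0.001 µM (0.105) and without Rs628 at 0.01 and 10 µM (0.133 and 0.187). At 0.001 µM lipogenesis (0.0291, 0.102 with the rat as a block) and hepatocyte identity (0.0252) were called with no member passing. They were lost at adjusted p = 0.556 and 0.172 with an estimated correlation and without Rs631 (0.0795 and 0.0702), and both also without Rs627 (0.374 and 0.667), where the median of lipogenesis was -0.05. Hepatocyte identity was also lost without the arrays at repeated positions (0.0684), and peroxisomal oxidation passed upward without these (0.0149) or without the arrays whose label ends in 2 (0.0148).

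Cyp1a2, a P450 induced through the aryl hydrocarbon receptor, was at least 2.91-fold higher at 0.001 µM on average over the times, with values under 5 set to 5 (1.82 ± 0.44 as measured, adjusted p = 0.721), 3.61-fold at 0.01 µM (2.15 ± 0.45, adjusted p = 0.00224), 3.10-fold at 0.1 µM (1.85 ± 0.45, adjusted p = 0.00214), 2.74-fold at 1 µM (1.65 ± 0.42, adjusted p = 0.00130) and 3.96-fold at 10 µM (2.15 ± 0.44, adjusted p = 4.97e-05), with the same sign in all 4 rats. At 0.1 µM this sign rests on almost no rise in Rs632, with values of 5.46, 4.57 and 5.17 at 2, 6 and 72 h. Its values at 0 µM were 5.66, 4.64 and 4.88. At 1 µM and 72 h Rs627 was lower than at 0 µM (4.05 against 5.75). The times differed: from 0.001 to 10 µM the change of Cyp1a2 went from 1.41 to 2.31 at 2 h, 2.11 to 3.42 at 6 h and 2.00 to 3.47 at 12 h, but from 2.06 to 1.56 at 24 h and 1.53 to 0.01 at 72 h (-0.04 at 1 µM). It was above 5 in 8 of 17 arrays at 0 µM and in 15 of 17 at 0.001 µM. The call was lost without Rs627 (0.147) or Rs628 (0.101) at 0.01 µM, without Rs627 at 0.1 µM (0.0513, where leaving out Rs632 gave a log2 change of 2.54), without Rs628 at 1 µM (0.0657), and with one value per rat at 0.01 (0.282) and 0.1 µM (0.0779). The list of xenobiotic metabolism, which holds it, was called upward at 0.001 µM with 0 of 11 members passing (1 over the list alone, 3.81e-07), as was the NRF2 list (0 of 11 members, 1.08e-07), both also with an estimated correlation (adjusted p = 0.00153 for each). At 0.01, 0.1, 1 and 10 µM the xenobiotic list had 1, 5, 6 and 6 members up and 0, 0, 3 and 3 down (1.89e-06, 0.00179, 0.0197 and 0.0200), the last pair lost at adjusted p = 0.117 and 0.129 with an estimated correlation and that at 1 µM without Rs628 (0.0516) and at 10 µM without the arrays at repeated positions (0.0540).

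The direct comparison of 10 µM with 1 µM, averaged over the times, gave no gene in limma. At an unadjusted p under 0.05 in limma there were 98, 352 with the rat as a block and 35 with one value per rat. Each of these numbers is fewer than expected by chance, so this test was conservative and does not exclude changes above 1 µM. Without Rs628 the comparison gave 3. Ehhadh differed by 0.06 ± 0.12, Pdk4 by 0.06 ± 0.20 and Cyp4a1 by -0.04 ± 0.13 (adjusted p = 1.00 each, n = 16 and 19). Shifts of mitochondrial oxidation (upward, 0.00112), lipid droplet genes (upward, 0.0461), lipogenesis (upward, 0.0461) and acute phase genes (downward, 0.0461) had median changes of 0.02, 0.04, 0.04 and -0.08 and no member passing. They were lost at adjusted p = 0.715, 0.715, 0.733 and 0.733 with an estimated correlation. Each was also lost without Rs631 (0.427, 0.462, 0.462 and 0.525), the first pair without Rs627 (0.753 and 0.894), all but the first without Rs632 (0.0783, 0.263 and 0.429), and the last with the rat as a block (0.0885). The first 3 were lost without the arrays at repeated positions (0.0762, 0.0979 and 0.148). With the block peroxisomal oxidation (0.00226) and other PPARα-responsive genes (0.00811) passed upward.

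Time in culture without the agent changed 301 genes between 2 and 72 h (20 higher, 281 lower, n = 3 and 4), with a median change of all genes of -0.17. The rises included Chac1, a glutathione-degrading enzyme of the ATF4 response (5.21-fold, 2.38 ± 0.39, adjusted p = 4.00e-05), and Ddit4, a stress-induced inhibitor of mTOR (5.18-fold, 2.37 ± 0.37, adjusted p = 2.09e-05). Rab30, a GTPase of the Golgi, fell 2.47-fold (-1.31 ± 0.19, adjusted p = 2.84e-06), Srxn1 2.20-fold (-1.14 ± 0.23, adjusted p = 0.00130, lost without Rs631 at 0.0551) and Acta2 1.82-fold (-0.86 ± 0.16, adjusted p = 4.04e-04, lost without Rs627 at 0.0513 or Rs631 at 0.0702). Each had the same sign in all 3 rats with both arrays. Ehhadh did not pass (-0.45 ± 0.26, adjusted p = 0.364). No list was called, though cholesterol synthesis passed downward with the rat as a block (0.163 without it, 0.00321 with it).

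The count over time in culture depended on the scaling. It was 81 after median centring (46 higher, 35 lower), 84 after quantile normalization (39 and 45), 1147 with the rat as a block (39 and 1108), 626 without the 5 arrays of low signal and 750 without the arrays at repeated positions. It was 71, 195, 57 and 64 without Rs627, Rs628, Rs631 and Rs632.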

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

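The tests without the 5 arrays of low signal and the splits that exchange arrays only within a rat were chosen after the results were seen.

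In groups of 4 arrays, 11 of 192 gene and group pairs had an array far from the other 3 by the ratio of gap to range, and chance flags about 1 in 20 groups. At 24 h and 1 µM the low-signal array of Rs631 stood apart for Aqp3 (gap ratio 0.913, value 3.98 against 9.74 to 10.28), Cxcl12 (0.885, 6.22 against 8.38 to 8.66) and Fads2 (0.965, 7.82 against 8.97 to 9.01). At 72 h and 0 µM, Rs627 stood apart for Serpine2 (0.868) and Dgat1 (0.916), and Rs628 for Lyz2 (0.960, 8.32 against 9.34 to 9.38) and Sdf2l1 (0.848). At 72 h and 1 µM, Rs632 stood apart for Cd68 (0.833), Rs628 for Cyp4a1 (0.950) and Rs627 for Mgll (0.882). At 6 h and 1 µM, Rs627 stood apart for Acat1 (0.858).

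The change at 1 µM differed between 72 and 2 h for 766 genes. Among named genes the difference was 3.45 for Cpt1b, 3.27 for Fabp1, 3.05 for Ehhadh, -4.37 for S100a6, -5.36 for Cyp2c11 and -0.76 for Angptl4. Of 100 splits of the arrays within each time, made without regard to the rat, 3 gave as many genes. The highest other gave 1042. Of the 64 splits that exchange arrays within a rat, 7 gave as many (highest other 1121). Each of these 7 left or fully reversed the 72 h groups and so kept the change at 72 h. Among splits that exchanged only part of the 72 h pairs the highest gave 105. Neither set can tell whether chance accounts for the difference between the times. Splits that mix treated and untreated arrays also remove the change that both times share. An equal change at both times was therefore not tested by splits.

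For the other counts, the splits of the same arrays compare as follows. At 2 h the 10 splits are too few for a share under 0.05, of which 1 reached the 33 genes and the highest other gave 0. Among splits made without regard to the rat, chance could be excluded at 6 h (180 genes, highest other 57, 1 of 35 splits), 12 h (478, 311), 72 h (2373, 787) and for time in culture (301, 23). The 8 splits that part every pair of arrays of one rat are too few for a share under 0.05, and their highest others gave 10, 195, 368 and 13. Chance could not be excluded at 24 h, where 2 of 35 splits reached 2619. The other, with 3138 genes, also parts every pair and places the 1 µM array of Rs628 with the 0 µM arrays, against the 1 µM arrays of Rs627, Rs631 and Rs632, of which 2 have low signal. For averages over times, with 100 splits each, chance could be excluded at 0.01 µM (61 genes, 2 splits), 0.1 µM (1263, highest other 130), 1 µM (3128, 892) and 10 µM (3488, 1978). Of 100 splits that exchange arrays only within a rat, 1 reached each of these counts, and the highest others gave 1, 788, 2219 and 2234. At 0.01 µM the highest other split made without regard to the rat gave 590 genes, several times the real count, which points to a structure of the arrays other than the concentration. The rat is a candidate, since the highest other split within rats gave 1 gene. Which arrays the split with 590 genes set apart was not examined. All 100 splits reached the count of 0 at 0.001 µM (highest other 0) and between 10 and 1 µM. There the highest other gave 2367, which points to such a structure as well (0 within rats). Its arrays were not examined either, and arrays of low signal are among those at 10 and 1 µM.

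At 24 h and 1 µM, 3.20 genes fell per gene that rose. The ratio was 1.21 without the 5 arrays of low signal, between the bounds set for and against these arrays as the source, so that their part cannot be told apart with the 2 arrays left. A shift common to most genes may account for it and cannot be told apart either: the ratio was 0.505 after median centring, but centring itself fixes the balance of falls and rises. A fall of the genes themselves that goes on in separate arrays also stays open: of the 1995 falling genes 96.4% had a negative change at 72 h, against 49.6% of the genes not called at 24 h. Taken against the median change of all genes at 72 h, 92.9% and 41.2% lay below it. Of the 1995 genes 985 also passed as falls at 72 h, where 310 would by unrelated lists.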

How the results depend on the processing

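The settings without the 5 arrays of low signal, without the 23 at repeated plate positions, without the 5 whose label ends in 2 and with 2 rats exchanged were chosen after the data were seen. Of 221 values of the 13 main counts under alternatives, 153 stayed within 1.5 times the count as reported and 68 did not. Of 340 values for the other 20 counts per time and concentration, 235 did. Of 2664 values for 157 named changes past the threshold, 2610 stayed past it in the same direction, 54 fell short and 0 reversed. Of 251 values for 15 named changes short of it, 3 passed. The totals for named changes do not measure robustness. Changing the filter, the prior or the minimum fold leaves the log2 change of a gene as it was, so no reversal was possible there. Other probe sets of a named gene were not compared. Most named changes were also picked by size or p in the same arrays, which favours calls that stay. Of 4576 values for gene lists, 4266 kept their side of the threshold, 173 lost a call and 134 gained one. The 3 reversed shifts were all at 0.001 µM: ω-oxidation with one value per rat (median change 0.0206), lipogenesis without Rs627 (-0.0506) and other PPARα-responsive genes without Rs628 (0.0247). Leaving out each rat gave -0.0506 to 0.0495 for lipogenesis and -0.0762 to 0.0247 for other PPARα-responsive genes there. Arrays near a log2 value of 5 cannot show falls of dim genes. Where no cause is given, it was not tested.

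With the rat as a replicate block the counts were 74, 416, 998, 4405 and 3564 at 2, 6, 12, 24 and 72 h, 166 and 2509 at 0.01 and 0.1 µM, 1584 for the difference between 72 and 2 h and 1147 for time in culture. With the 2 rats at 12 h exchanged in that block they were 86, 474, 1118, 4668, 3703, 222, 2714, 1677 and 1368. The block changed no other main count by more than 1.5 times, no other named call than that of Cpt1a at 2 h (Fgf21 at 2 h passed only with the exchange), and among list calls those given beside their results and that of genes typical of fat cells at 0.01 µM (0.0560, 0.00817 with the block).

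The arrays of the compared time alone gave 9 genes at 2 h and 259 at 12 h, from fewer residual degrees of freedom. One value per rat gave 1, 604 and 909 at 0.01, 0.1 and 10 µM, from 4 values that average different times in different rats. Every probe set as its own feature tested more features and gave 54 at 2 h, 721 at 12 h, 4912 at 1 µM, 5551 at 10 µM and 471 for time in culture. A minimum of 1.5-fold left 315, 1598 and 1401 at 12, 24 and 72 h, 16, 232, 592 and 755 from 0.01 to 10 µM, and 108 for time in culture. Time in culture also gave 1357 with no filter, 84 after quantile normalization and 81 after median centring. Without the 5 arrays of low signal 1292 genes passed at 24 h and 626 for time in culture. Without the 23 arrays at repeated positions 1413 passed at 24 h, 1235 for the difference between 72 and 2 h and 750 for time in culture, and without the 5 whose label ends in 2 no main count moved by more than 1.5 times.

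Leaving out each rat gave 10 to 22 genes at 2 h, 104 to 140 at 6 h, 284 to 729 at 12 h, 867 to 3372 at 24 h and 1520 to 2188 at 72 h. It gave 0 at 0.001 µM (12 to 171 at an unadjusted p under 0.05 in limma), 24 to 108 at 0.01 µM, 605 to 1693 at 0.1 µM, 1872 to 3427 at 1 µM and 2159 to 3826 at 10 µM. Between 10 and 1 µM it gave 0 to 3, for the difference between 72 and 2 h 303 to 618 and for time in culture 57 to 195. Rats are named beside the counts and named genes they moved. Filtering at log2 7 and the intensity trend with a robust prior moved none of the 13 main counts by more than 1.5 times.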

Other observations

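The tests on Cyp1a2 and the distance test on exchanged labels were chosen after the results were seen, and the tests on gene lists before the data were examined.

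Several gene groups not described above moved in parts at 72 h and 1 µM. Of 12 bile acid genes 4 rose and 2 fell (camera adjusted p = 0.232). Cyp8b1, the sterol 12α-hydroxylase of cholic acid synthesis, rose at least 8.90-fold with values under 5 set to 5 (3.28 ± 0.37 as measured, above 5 in 3 of 4 arrays at 0 µM, adjusted p = 2.14e-11), Nr1h4, the bile acid receptor, 2.21-fold (1.14 ± 0.27, adjusted p = 5.53e-04) and Abcb11, the bile salt exporter, 1.5-fold (0.58 ± 0.13, adjusted p = 4.30e-04), while Abcc2 fell as given above. Of 11 genes of xenobiotic metabolism 5 rose and 3 fell (0.0571). Nr1i3, the receptor CAR, rose at least 4.20-fold (2.57 ± 0.42 as measured, adjusted p = 1.28e-06, above a log2 value of 5 in 4 of 4 treated arrays and 1 of 4 at 0 µM), Cyp3a18 3.26-fold (1.70 ± 0.32, adjusted p = 2.17e-05) and Por, the electron donor of microsomal P450s, 2.92-fold (1.55 ± 0.18, adjusted p = 4.96e-11).

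Of 17 genes of cholesterol synthesis and uptake 3 rose, 2 fell and 12 did not pass at 72 h (0.473). Insig1, a sensor that restrains sterol synthesis, rose 1.52-fold (0.61 ± 0.15, adjusted p = 9.04e-04, lost without Rs627 at 0.0538) and Msmo1, a sterol demethylase, fell 1.46-fold (-0.55 ± 0.16, adjusted p = 0.00533, the same sign in 3 of 4 rats, lost without Rs631 at 0.163 or Rs632 at 0.0707). Of 14 genes of the ATF4 and unfolded protein response 1 rose and 3 fell (0.512). Herpud1, of endoplasmic reticulum degradation, rose 1.53-fold (0.61 ± 0.12, adjusted p = 2.94e-05), Sdf2l1, a chaperone partner, fell 2.43-fold (-1.28 ± 0.22, adjusted p = 5.03e-06) and Xbp1, a transcription factor of that response, 1.42-fold (-0.51 ± 0.11, adjusted p = 1.77e-04). Of 14 cell cycle genes 1 rose and 3 fell (0.265). Tk1, thymidine kinase, rose 1.75-fold (0.81 ± 0.22, adjusted p = 0.00280, lost without Rs632 at 0.0697) and Tyms, thymidylate synthase, was at least 1.52-fold lower (adjusted p = 3.75e-05).

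Averaged over the times, the mean of Cyp1a2 was above that at 0 µM at every concentration, though it did not pass at 0.001 µM (adjusted p = 0.721), and at 72 h its change was -0.04 and 0.01 at 1 and 10 µM. A response that grows with concentration cannot be told apart, since the times differ: its slope among the 83 treated arrays was -0.00576 ± 0.0973 per 10-fold concentration, where that of Ehhadh was 1.00 ± 0.06, but by time it was 0.18 ± 0.21, 0.28 ± 0.21, 0.26 ± 0.22, -0.17 ± 0.20 and -0.48 ± 0.20 at 2, 6, 12, 24 and 72 h. Against 1 rat alone carrying the difference, 4 of 4 rats had a mean difference above 0.5 at 0.001 µM (1.94, 2.63, 1.67 and 1.5), that of Rs628 from its 72 h arrays alone and the others at different times: 2.74 at 2 h and 0.39 at 72 h in Rs631, but -0.33 and 3.09 in Rs632. A factor shared by the treated wells and missing from the 0 µM wells may account for it and cannot be told apart from the agent, since the labels do not separate them, and it leaves open the lack of a change at 1 and 10 µM at 72 h; the median of the 3 measured Cyp1 genes was 0.649 at 0.001 µM, while genes of mitochondrial oxidation had a median of -0.01. A biological response already complete at 0.001 µM stays open for part of the arrays and was not tested. In Rs632 at 2 h Cyp1a2 was 5.66 at 0 µM and 5.33, 5.69 and 5.46 from 0.001 to 0.1 µM. It was 7.28 and 8.57 at 1 and 10 µM. At 6 h these values were 4.64, then 4.87, 5.14 and 4.57, then 6.85 and 8.20. Neither a shared factor nor a complete response accounts for these arrays without a rise. Rs627 and Rs631 were already higher at 0.001 µM at both times.

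The 12 h 0 µM arrays labelled Rs627 and Rs628 (the latter with a label that ends in 2) resembled the other rat over 50 genes that tell the rats apart in the other 98 arrays. Each was farther from its labelled rat than from the other (ratios 5.68 and 4.90), and of 99 arrays tested these were the 2 nearest to another rat. Against a mixture of RNA from both rats in each array, they lay at 0.983 and 1.05 of the way to the other rat. An exchange of the 2 labels is the candidate explanation, and it leaves the primary model untouched because both arrays are in the same group, while signs by rat, one value per rat and values without either rat rest on the labels as given. No biological explanation was tested.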
